A study of Mus musculus with 37 samples.

How the data were processed

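Lung RNA of female C57BL/6 mice was measured 1 and 28 days after a single intratracheal instillation of hydrophobic rutile titanium dioxide nanoparticles of 20 nm, per the labels. The 37 arrays analysed here cover 4 doses (0, 54, 162 and 486 µg per animal) at both days. On day 1 the groups held 5, 5, 4 and 5 arrays in order of dose, and on day 28 they held 5, 4, 5 and 4. The labels give RNA from random tissue sections with n = 5 per group and do not say whether sections shared an animal, so each array was assumed to be 1 animal. They do not state what the control animals were instilled with. On 1 of the day 1 controls the dose label is a word for control in place of 0, and this array was pooled with the other controls. An 18 µg dose and a day 90 collection appear in the design text and were not analysed here.

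Each array carried lung RNA in Cy5 and a universal mouse reference RNA in Cy3, per the labels, with the same dye orientation on all 37 arrays. A log ratio is therefore lung over reference, and the reference cancels between groups. Dye effects that are the same on all arrays cancel too, and were not measured by a dye swap.

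The deposited scanner files hold spot intensity in both channels, made with Agilent Feature Extraction 11.0.1.1 per the file headers. Each array has 45018 spots, of which 1639 are control spots, and 41174 probes. The fixed design assumed mean signals, but the files used here give median pixel intensity per spot and per local background, and medians were used in their place. The same files hold a log10 ratio of processed Cy5 over processed Cy3, computed by the scanner software with its own background subtraction and dye normalization, per the file headers. A separate table of processed values by the authors is on a log2 scale as found by comparison. Its columns followed log2 of Cy5 over Cy3 after loess without background subtraction (r 0.993 to 0.998 across probes, slope 0.986 to 0.996), and had medians from -0.057 to -0.027. Its software and exact normalization steps are not given in the sources used here.

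Gene names came from a RefSeq table of assembly GRCm38.p6 through the transcript accessions of the probes. A symbol was found for 27479 of the 41174 probes (18749 symbols), and 13695 probes kept the identifier of the array design. The file headers name another genome build, so no coordinates are given.

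For this work the background was corrected with normexp (offset 50), and each array was normalized by loess with control spots and non-uniform outlier spots at weight 0. Outlier spots, 0 to 20 per array, were set to missing. No spot was saturated. Spots of 1 probe were averaged. Probes were kept where Cy5 was well above background on at least 3 arrays of at least 1 group, which left 29648 probes. A gene with several kept probes (5634 genes) was represented by the probe of highest mean signal. This gave 22385 genes, 15511 with a symbol and 6874 without.

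Median Cy5 intensity per array ran from 118 to 222.5 and median Cy3 from 42.0 to 122.5. The share of probes well above background was 46.8% to 73.1% in Cy5 and 50.9% to 80.6% in Cy3. The number of arrays, 4 or 5 per group, limits the precision, and the median standard error of a difference from controls was 0.17 to 0.18 on the log2 scale.

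Group means were fitted to all 37 arrays in 1 linear model per gene with limma 3.58.1 in R 4.3.3, with 29 residual degrees of freedom, moderated by empirical Bayes with a mean-variance trend. All gene-level p-values are from limma's two-sided moderated test, adjusted by the Benjamini-Hochberg method over 22385 genes within a comparison, with 0.05 as the threshold. There were 12 comparisons: each dose against 0 µg at each day, 486 against 162 µg at each day, the difference of each dose's response between days, and day 28 against day 1 in the controls. Counts at an unadjusted p under 0.05 in limma are also given, where chance gives 5% of genes. That share was 7.42% for 486 against 0 µg on day 1. In the other comparisons it was 1.03% to 4.37% without a block, so their counts are not read as a response. Folds are on the scale of log2 values after an offset of 50, which understates the change of dim genes.

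There were 35 gene lists, 16 of pathways and 19 of cell type markers, among them tissues that a lung section could hold by accident. Some genes belong to more than 1 list, among them Timp1, Ctsk, Ccl17 and Il1r2, so the list results are not independent. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 35 lists within a comparison. The test was repeated with the correlation estimated from the data (0.0516 to 0.765 per list) and with fry, which tests whether the genes of a list moved one way on balance. Members were counted as risen or fallen over all genes and adjusted over the list alone. For the list tests, 69 missing values were filled with their group mean, and the fits with slide as a random block or with array weights used the same filled values.

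The lists, comparisons, thresholds, alternatives and the rule for naming genes were fixed before the data were examined. Genes were named by the largest log2 differences among those past the threshold with a symbol and with groups that did not overlap: up to 10 each way at 486 µg, 5 at the other doses and 3 for 486 against 162 µg. Where none passed, the 3 of smallest p were named. From each list described, up to 4 members past the threshold were added, or the 2 of smallest p. Genes named under 1 comparison were also given at other doses. A member that this rule named is not reported here, and no other took its place. Some choices were made after the results were seen: a list member counted as past the threshold over all genes or over the list alone, and a list was described where the preset test passed and either the estimated one passed or at least 2 members passed over the list alone. The lists shown in the figure were also chosen then.

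The arrays came from 11 slides and 5 scan days, which held several groups each. After group means were removed, arrays of the same slide correlated across genes at a median r of 0.344 and arrays of different slides at -0.0683. Each result was therefore also computed with slide as a fixed block and within each slide that held both groups. Pairs of arrays correlated at r 0.677 to 0.992 across genes, and no pair held identical values. The 2 most alike of 666 pairs were both within a group and on different slides, where 10.2% of pairs are within a group: replicates 4 and 5 of the 162 µg group on day 28 (r 0.992) and replicates 3 and 5 of the 486 µg group on day 1 (r 0.988). The labels do not say whether these arrays share an animal, and if they do, n is 4 in these groups. Each result was therefore also computed with the 2 pairs averaged, an alternative added after seeing the data. Alternatives covered the background correction, the scanner's log ratio, the authors' processed values, normalization between arrays, filters on dim probes, the choice of probe, slide or scan day as blocks, array weights, a fit over the compared groups, a minimum of 1.5-fold, and leaving out each array. Leaving out the arrays of scan day 1, which lay apart on the first principal component, and of slide 4, which was dim in Cy3, was added after seeing the data, as were the medians without single arrays of lists that were not carried through the other alternatives.

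The limma steps were tested on simulated data with 22385 genes, 200 of them changed by a set fold, in 10 sets with the group sizes and spread of 486 µg against 0 µg, independent noise and no slide effect. A further list of genes was shifted upward in the same group, and calls of its members were not counted as false. For day 1, 41.6% of 1.5-fold changes, 81.3% of 2-fold changes and 98.8% of 4-fold changes were recovered, and 4.92% of calls were false. For day 28 the shares were 33.7%, 74.5% and 97.9%, with 5.78% of calls false.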

Results

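Expression was measured on 37 arrays of lung RNA, 19 collected 1 day and 18 collected 28 days after instillation of 0, 54, 162 or 486 µg of hydrophobic titanium dioxide nanoparticles. The comparisons ask which genes differed from the controls at each dose and day, whether the highest dose differed from the dose below it, and whether a response at day 28 differed from that at day 1. Values are log2 ratios of lung over a common reference, given as mean ± SD, and differences carry the SE of the limma fit.

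On day 1 after 486 µg, 3 serum amyloid genes, Timp1, Lcn2 and the chemokine gene Ccl17 were higher than in controls. Saa3, an acute phase apolipoprotein, was 38.2-fold higher (3.95 ± 0.74, n = 5, against -1.31 ± 0.92, n = 5). Saa1 was 10.7-fold and Saa2 6.14-fold higher, and the 3 genes are paralogs of similar sequence. Timp1, an inhibitor of matrix metalloproteinases, was 9.40-fold higher on the brighter of its 2 probes. Lcn2, which encodes a protein that sequesters bacterial siderophores, was 5.52-fold higher, and the chemokine Ccl17 was 2.96-fold higher. Asgr1, a subunit of the asialoglycoprotein receptor, fell by 1.04 on the log2 scale, and Chchd10, which encodes a mitochondrial protein, fell by 0.98. The controls varied more than the exposed arrays for Chchd10 (SD 0.62 against 0.23), and replicate 2 of the controls stood apart. That array also had the highest adipose marker score of day 1 (6.67). Its tissue makeup was not tested as a source of the Chchd10 difference.

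In all, limma called 14 genes at 486 µg on day 1, 11 higher and 3 lower. An unadjusted p under 0.05 was found for 1662 genes (7.42%, where chance gives 5%). The log2 differences were 5.26 ± 0.70 (SE) for Saa3 with an adjusted p of 2.41e-04, 3.42 ± 0.47 for Saa1 (2.57e-04), 3.23 ± 0.54 for Timp1 (0.00369) and 2.62 ± 0.42 for Saa2 (0.00308). Adjusted p was 0.0175 for Lcn2, 0.0145 for Ccl17 and Asgr1, and 0.0445 for Chchd10. The tubulin gene Tuba1c (1.02), Tmem176a (0.74) and H13 (0.83) also rose. The log2 difference was 2.05 on the other probe of Timp1. The 3 probes of H13 disagreed, from -0.37 to 0.83, and its average over probes was not called. The alarmin Il33 rose by 1.26 with overlapping groups. Ctps (1.27) and Atp6v0e2 (-0.65, and -0.28 on its other probe) were called with overlapping groups and are named because their values were seen. With slide as a block, 38 genes were called, 24 higher and 14 lower, and 7 of the 14 were among them. Saa3 (adjusted p 0.0187), Saa1, Timp1 and Saa2 remained called, while Lcn2 (0.0814), Ccl17 (0.0769), Asgr1 (0.0545) and Chchd10 (0.0603) were not. All 14 genes, picked for this difference, kept their direction in each of the 3 slides that held both groups, as 31.9% of all genes did, and Saa3 differed there by 4.21 to 7.05. The count was 6, 5, 26 and 5 without replicate 2, 3, 4 or 5 of the 486 µg group, and 7 and 6 without replicate 1 or 4 of the controls. Replicates 3 and 5 of the 486 µg group were nearly alike (r 0.988), and with the most alike pairs of arrays averaged 5 genes were called: Saa3, Saa1, Timp1, Saa2 and H13.

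**Figure D1:**
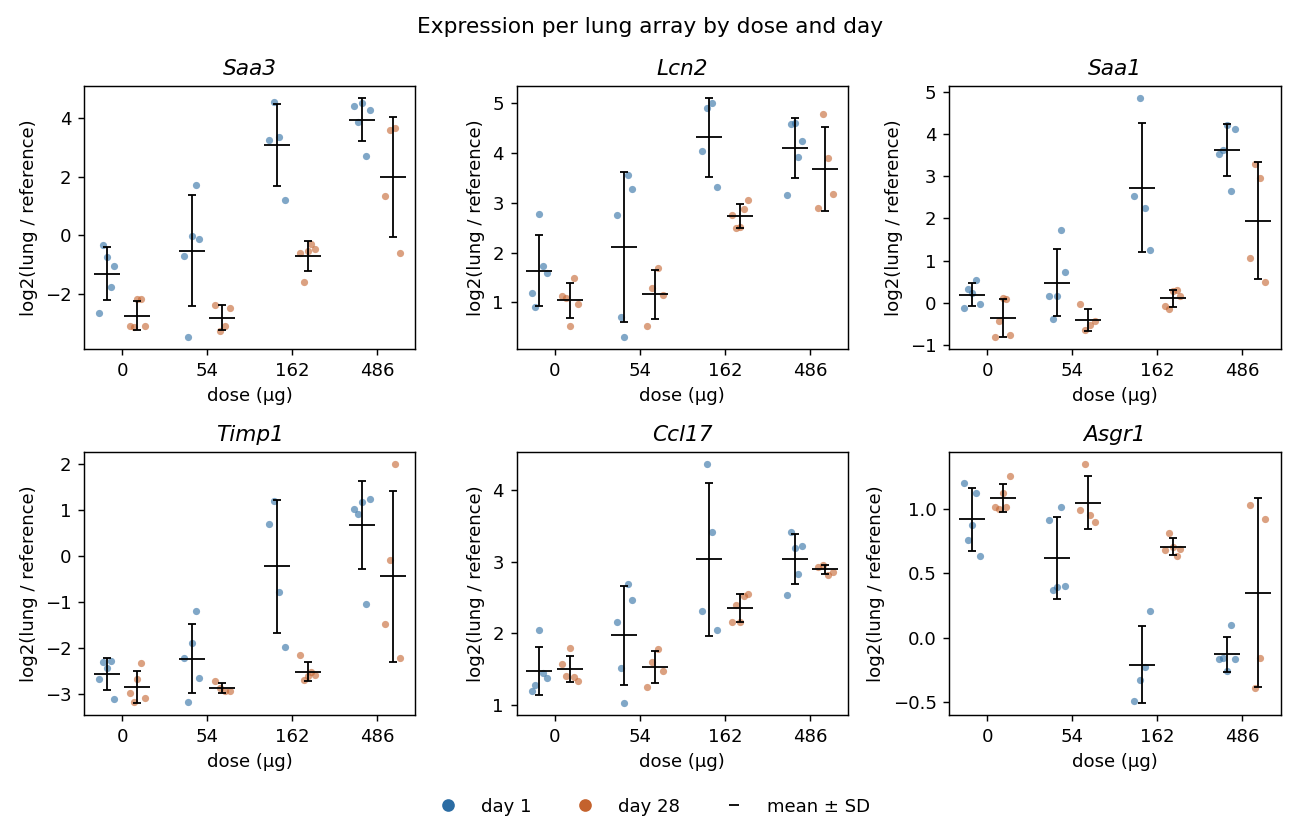
Log2 ratio of lung over reference (vertical axes) for 6 genes in each of the 37 arrays, by dose in µg (horizontal axes), with day 1 in blue, day 28 in orange, and bars for the mean ± SD. At 486 µg on day 1 all 5 Saa3 values lie above all 5 controls (3.95 ± 0.74 against -1.31 ± 0.92), and the 4 values on day 28 are spread widely (1.99 ± 2.04).

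Gene groups at 486 µg on day 1 were led by the acute phase proteins, of which 5 of 22 rose over all genes and 12 when adjusted over the list alone. Their median difference was 0.90 (camera adjusted p = 1.31e-25, and 0.00169 with an estimated correlation), and it was 0.40 to 1.21 within the 3 slides. Sterol biosynthesis genes rose together: 9 of 22 passed when adjusted over the list alone and 0 over all genes, among them lanosterol synthase Lss (0.69), Cyp51 (0.68) and Fdps (0.59). The list median was 0.36 (adjusted p = 4.82e-11, and 0.00169 with an estimated correlation). Among matrix proteases and inhibitors Timp1 and the urokinase receptor Plaur (0.49) rose, 2 of 20 adjusted over the list alone and 1 over all genes (Timp1), with a list median of 0.25 (adjusted p = 1.06e-05, and 0.0129 with an estimated correlation). With slide as a block and an estimated correlation, the adjusted p was 0.0652 for acute phase proteins, 0.0548 for sterol biosynthesis and 0.0372 for matrix proteases.

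Other lists at 486 µg on day 1 passed with the preset correlation and not with an estimated one, 16 of 35 against 3. With fry 6 of 35 passed. Of 24 chemokines, 4 rose when adjusted over the list alone and 1 over all genes (Ccl17), the 4 including the monocyte attractants Ccl7 (1.90) and Ccl2 (1.42) and the neutrophil attractant Cxcl1 (1.67). The chemokine list had an adjusted p of 6.01e-05, and 0.218 with an estimated correlation. Neutrophil markers had 3 of 13 members rise when adjusted over the list alone and 0 over all genes: Il1r2 (1.26), Cxcr2 (1.06) and Trem1 (0.41), with a list adjusted p of 1.28e-05, and 0.0793 with an estimated correlation. For cytokines, 4 of 24 rose over the list alone and 1 over all genes (Il33), the 4 being Il33, Il1r2, Il1b (1.01) and the prostaglandin E synthase Ptges (0.73), with adjusted p = 0.107 with an estimated correlation. In the matrix and fibrosis list, Spp1 (1.37), the gene of osteopontin, and the basement membrane collagen Col4a1 (0.79) were the 2 of 28 to rise over the list alone, 0 did over all genes, and the adjusted p was 0.171 with an estimated correlation. Ccl17 and Arg1 (0.92) were the 2 of 18 alternative macrophage activation genes to rise over the list alone, 1 over all genes (Ccl17), with an adjusted p of 0.00456, 0.169 with slide as a block, and 0.218 with an estimated correlation. Clock genes moved both ways, 8 of 16 up and 2 down when adjusted over the list alone and 0 over all genes, with Dbp (1.1), Per1 (0.82) and Nr1d1 (0.73) higher and Arntl (-0.90) lower. That list had an adjusted p of 0.00118, and 0.0793 with an estimated correlation. Adipose markers, measured beside these lists, had a median of -1.46 with 0 of 7 members above 0 (adjusted p = 1.28e-05, and 0.196 with an estimated correlation), and cardiac muscle markers had a median of -0.51 with 0 of 13 above 0 (0.00420, and 0.533 with an estimated correlation). Most of the adipose value came from replicate 2 of the controls, without which it was -0.46, and the cardiac median was -0.27 without replicate 5 of the controls and -0.88 without replicate 1 of the 486 µg group. Dbp was called over all genes without replicate 3 of the controls, and Il1r2 without replicate 1 or 4 and Arg1 without replicate 4 of the 486 µg group.

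After 162 µg on day 1, Saa3 was 21.0-fold higher than in controls (3.08 ± 1.39, n = 4, against -1.31 ± 0.92, n = 5), and Lcn2 was 6.41-fold higher (4.32 ± 0.79 against 1.64 ± 0.71). Asgr1 fell by 1.12 on the log2 scale. These were the 3 genes called by limma, with adjusted p of 0.0255, 0.0429 and 0.0429 and differences of 4.39 ± 0.74 (SE), 2.68 ± 0.50 and -1.12 ± 0.21. All 3 were also called at 486 µg in the same direction. An unadjusted p under 0.05 was found for 702 genes, 3.14% of all, which is fewer than the 5% that chance gives. In a fit with slide as a block limma called 0 genes (1832 at an unadjusted p under 0.05), with adjusted p of 0.0967 for Saa3, 0.174 for Lcn2 and 0.0967 for Asgr1. Within the 4 slides that held both groups the difference was 2.24 to 5.89 for Saa3, 1.72 to 4.00 for Lcn2 and -1.69 to -0.42 for Asgr1. The count was also 0 when any 1 of replicates 1, 2 and 3 of the 162 µg group or replicates 1, 4 and 5 of the controls was left out, 5 without replicate 3 of the controls, and 9 without replicate 4 of the 162 µg group. It was 0 as well with the most alike pairs of arrays of other groups averaged.

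Inflammatory lists moved upward at 162 µg on day 1 and passed with an estimated correlation. Of 22 acute phase proteins, 9 rose when adjusted over the list alone, among them Saa1 (2.53) and Timp1 (2.34), and 2 over all genes, Saa3 and Lcn2. The list median was 0.72 (adjusted p = 3.12e-25, and 0.00183 with an estimated correlation). Among 24 chemokines, 11 rose over the list alone and 0 over all genes, with Ccl4 (1.88), Cxcl5 (1.85), Ccl7 (1.67) and the interferon-induced Cxcl10 (1.58) at the top and a list median of 0.71 (1.75e-16, and 0.00556 with an estimated correlation). Neutrophil markers had 6 of 13 members rise over the list alone and 0 over all genes, including Cxcr2 (1.04), S100a8 (0.98) and Clec4d (0.83), with a median of 0.78 (4.32e-13, and 0.00183 with an estimated correlation). For cytokines, 6 of 24 rose over the list alone and 0 over all genes, led by Csf2 (1.34), the growth factor of alveolar macrophages, Il1b (1.19), the decoy receptor Il1r2 (1.16) and the antagonist Il1rn (1.1), with an adjusted p of 2.86e-09, and 0.00547 with an estimated correlation. Timp1 was the 1 of 20 matrix proteases and inhibitors to rise over the list alone, 0 did over all genes, and the list median was 0.34 (1.63e-08, and 0.00183 with an estimated correlation). Within the 4 slides the list medians were 0.57 to 1.1 for acute phase proteins, 0.36 to 2.00 for chemokines and 0.38 to 0.96 for neutrophil markers. Without replicate 3 of the 162 µg group the chemokine median was 0.38, the cytokine median 0.07 in place of 0.15, and Cxcl10 0.74. The 5 lists had adjusted p from 0.0209 to 0.0396 with slide as a block and an estimated correlation.

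Recruited macrophage markers and clock genes passed at 162 µg on day 1 with the preset correlation and not with an estimated one. The lipopolysaccharide co-receptor Cd14 (1.12) and Ly6c2 (0.62) were the 2 of 16 macrophage markers to rise over the list alone, 0 did over all genes, and the list had an adjusted p of 0.00396, 0.0528 with slide as a block, and 0.439 with an estimated correlation. The median of that list, 0.20, was -0.07 without replicate 3 of the 162 µg group (adjusted p = 0.379), 0.01 without replicate 1 of the controls (0.0885), 0.03 without replicate 2 of the 162 µg group, 0.07 without replicate 4 of the controls, and 0.48 and 0.42 without replicate 1 of the 162 µg group or replicate 2 of the controls. Dbp (1.13) rose and Arntl (-0.87) fell over the clock list alone, with a list adjusted p of 0.0367, and 0.265 with an estimated correlation. The clock list did not pass without replicate 1 or 4 of the 162 µg group or replicate 2 or 4 of the controls. Adipose markers had a median of -1.24 with 0 of 7 members above 0 (1.07e-04, and 0.265 with an estimated correlation), and cardiac muscle markers one of -0.34, which was not past the threshold (0.0884). Without replicate 2 of the controls the adipose median was -0.18, and without replicate 5 of the controls the cardiac one was 0.06. Interferon response genes had a median of 0.35 (2.51e-05, and 0.439 with an estimated correlation), which was -0.08 without replicate 3 of the 162 µg group (score 2.16, others 0.09 to 1.15) and 0.67 without replicate 1. Of 35 lists, 17 passed with the preset correlation, 5 with an estimated one and 5 with fry.

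At 54 µg on day 1 no gene was called. The 3 genes of smallest p did not pass: the proliferation marker Mki67 (-0.82 ± 0.20, SE), Slc35g1 (0.61 ± 0.15) and Lynx1 (-0.64 ± 0.17), each with an adjusted p of 1.00 in limma. Lynx1 differed by -0.39 without replicate 2 of the controls. Saa3 differed by 0.78 ± 0.70 and Lcn2 by 0.48 ± 0.47, less than 2 standard errors. The count was 0 in limma without and with slide as a block, with 471 and 1136 genes at an unadjusted p under 0.05. Of 35 lists, 11 passed with the preset correlation, and 0 with an estimated one or with fry. Clock genes had 2 of 16 members rise over the list alone and 0 over all genes, Dbp (1.01) and Nr1d1 (0.77), with a list adjusted p of 8.21e-04, and 0.171 with an estimated correlation. Adipose markers had a median of -0.92 with 0 of 7 members above 0 (adjusted p = 0.00150, and 0.645 with an estimated correlation), and cardiac markers one of -0.43 (0.00583, and 0.673). The adipose median was -0.02 without replicate 2 of the controls, and the clock median of 0.27 was 0.16 without replicate 1 of the 54 µg group. Replicate 3 of the 54 µg group followed the authors' values, which lack background subtraction, least after the background correction used here (r 0.861) and had the lowest array weight (0.219). Without it the medians were -0.49 for adipose and -0.08 for cardiac markers, and the cardiac one was -0.80 to -0.08 without any 1 array.

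On day 28 after 486 µg, Saa3 was 26.7-fold higher than in controls (1.99 ± 2.04, n = 4, against -2.75 ± 0.51, n = 5). Lcn2 stood at 3.69 ± 0.84 against 1.04 ± 0.35, a 6.26-fold difference with an adjusted p of 0.0522, which lay past the threshold in 8 of 16 alternatives (4.96e-04 to 0.197) and without replicate 4 of the 486 µg group. Ccl17 differed by 1.39 ± 0.31 (SE) and Asgr1 by -0.73 ± 0.21, with adjusted p of 0.128 and 0.531. Saa3 was the 1 gene called by limma, with a difference of 4.74 ± 0.74 and an adjusted p of 0.00644. An unadjusted p under 0.05 was found for 812 genes, 3.63% of all, which is fewer than the 5% that chance gives. Blocking by slide, Saa3 had an adjusted p of 0.0812 and 0 genes were called by limma, with 1058 at an unadjusted p under 0.05. Within the 3 slides that held both groups Saa3 was 1.58 to 6.80 higher. The Saa3 call was lost without replicate 2 (adjusted p = 0.147) or replicate 3 (0.0522) of the 486 µg group, without the arrays of scan day 1 (0.143) or slide 4 (0.162), and in a fit over the compared groups. The count of genes was 0 without replicate 2, 11 without replicate 4 and 2 without replicate 4 of the controls.

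Upward shifts of 6 lists, some of which share members, passed with an estimated correlation at 486 µg on day 28. Of 24 chemokines, 11 rose over the list alone and 0 over all genes, led by Cxcl5 (2.59), Ccl7 (2.55), Ccl2 (2.23) and Cxcl1 (2.23). Their median was 0.60 (adjusted p = 1.11e-20, and 0.00292 with an estimated correlation). Acute phase proteins had 9 of 22 members rise over the list alone, among them Lcn2 (2.65), Timp1 (2.41) and Saa1 (2.30), and 1 over all genes, Saa3, with a median of 0.58 (5.98e-21, and 0.00292 with an estimated correlation). For cytokines, 6 of 24 rose over the list alone and 0 over all genes, including Csf2 (1.13), Il1rn (0.86), Ptges (0.79) and Il33 (0.72), with an adjusted p of 2.88e-08, and 0.0106 with an estimated correlation. Ptges (-0.02) and Il33 (-0.04) were lower in 1 of 3 slides. Matrix proteases and inhibitors had 5 of 20 rise over the list alone and 0 over all genes: beside Timp1 these included cathepsin K (Ctsk, 1.19), Mmp19 (0.48) and Mmp12, macrophage elastase. No size is given for Mmp12, which was not well above background on any control array. It had an adjusted p of 1.00 over all genes and was lower in 1 of 3 slides. The protease list had a median of 0.38 (6.09e-08, and 0.00292 with an estimated correlation). Lysosome and phagosome genes moved upward with 26 of 27 members above 0, a median of 0.25 and an adjusted p of 9.73e-10 (0.0219 with an estimated correlation). Legumain (Lgmn, 0.62) and cathepsin B (Ctsb, 0.60) were the 2 that rose over the list alone, and 0 did over all genes. In the sterol list 0 of 22 members passed over the list alone or over all genes, with smallest p for Idi1 (0.54) and Mvd (0.37), while the list as a whole had a median of 0.23 (1.67e-06, and 0.0181 with an estimated correlation). Slide medians ran from 0.36 to 1.36 for chemokines, 0.37 to 1.16 for acute phase proteins and 0.05 to 0.66 for lysosome genes. With slide as a block and an estimated correlation, the adjusted p was 0.0779 for lysosome genes and 0.060 for sterol genes. Without replicate 2 of the 486 µg group Il1rn differed by 0.49, Ctsb by 0.33 and the lysosome median was 0.16. Without replicate 3 of that group Timp1 differed by 1.59, Ptges by 0.46 and Idi1 by 0.36, and the medians were 0.99 for chemokines and 0.38 for lysosome genes.

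Macrophage and complement lists at 486 µg on day 28 passed with the preset correlation and not with an estimated one. Of 18 alternative macrophage activation genes, 5 rose over the list alone and 0 over all genes, including Ccl17, the scavenger receptor Msr1 (1.23), Gpnmb (1.22) and Trem2 (1.20), with an adjusted p of 1.20e-04, and 0.0743 with an estimated correlation. Recruited macrophage markers had 3 of 16 rise over the list alone and 0 over all genes, Ms4a7 (1.29), Cd14 (1.05) and Ly6c2 (0.64), with 3.32e-04, and 0.341 with an estimated correlation. Complement genes C3 (0.98), C1ra (0.70) and C3ar1 (0.49) were the 3 of 15 to rise over the list alone, 0 did over all genes, and the list had an adjusted p of 4.14e-04, and 0.327 with an estimated correlation. Without replicate 2 of the 486 µg group the medians of the macrophage and complement lists were -0.13 and -9.86e-04 in place of 0.20 and 0.26, and neither passed, while without replicate 3 they were 0.51 and 0.52. The macrophage median was also 0.35 without replicate 1 of the 486 µg group and 0.13 without replicate 2 of the controls. Without replicate 2 of the 486 µg group Gpnmb differed by 0.60, Trem2 by 0.68, Ms4a7 by 0.80 and C3ar1 by 0.30, and Trem2 was lower in 1 of 3 slides (-0.13). Clock genes had 3 of 16 rise and 1 fall over the list alone and 0 over all genes, with Dbp (1.36), Bhlhe40 (0.97) and Nr1d2 (0.89) higher and Npas2 (-0.24) lower (0.0155, and 0.192 with an estimated correlation). Npas2 was well above background on 2 of 4 arrays at 486 µg and on 5 of 5 controls. The clock median of 0.22 was 0.11 without replicate 1 and 0.35 without replicate 2 of the 486 µg group, and the list did not pass without replicate 1 or 3 of that group or replicate 1 of the controls. The matrix and fibrosis list had 1 of 28 members rise over the list alone, 0 over all genes, and a median of 0.03 (0.00110, and 0.118 with an estimated correlation). Adipose markers had a median of -0.56 (0.0911) and cardiac muscle markers one of -0.18 (0.462), neither past the threshold, and these were -0.10 and 0.09 without replicate 1 of the controls.

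Of 35 lists at 486 µg on day 28, 19 passed with the preset correlation, 6 with an estimated one and 4 with fry. Among those that passed with the preset correlation and not with an estimated one, structural cell markers were lower. Endothelium markers had a median of -0.45 with 0 of 12 members above 0 (adjusted p = 0.00129, and 0.377 with an estimated correlation), fibroblast markers one of -0.41 (0.0167, and 0.352), smooth muscle markers one of -0.26 (0.00300, and 0.327) and ciliated cell markers one of -0.39 (0.0332, and 0.619). Against the same controls, ciliated cell markers had medians of -0.51 at 54 µg (-0.12 without replicate 1 of that group) and -0.19 at 162 µg. Smooth muscle markers had one of -0.42 at 162 µg (-0.23 without replicate 1 of the controls). Lower medians of these 2 lists were therefore not limited to the highest dose. Cell cycle genes had a median of 0.33 with 25 of 27 above 0 (1.99e-09, and 0.212), and interferon response genes one of 0.34 (7.00e-06, and 0.369). The interferon median was -0.06 without replicate 2 of the 486 µg group (score 2.47, others 0.21 to 1.04), and 0.54 and 0.67 without replicate 1 or 3. Without replicate 3 of that group the medians were -0.24 for endothelium, -0.20 for fibroblast and -0.08 for ciliated cell markers. Without replicate 1 they were -0.29 for endothelium and -0.23 for ciliated cell markers, which were at -0.62 without replicate 4, and that of smooth muscle markers was -0.14 without replicate 1 of the controls and -0.15 without replicate 2 of the 486 µg group.

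**Figure D2:**
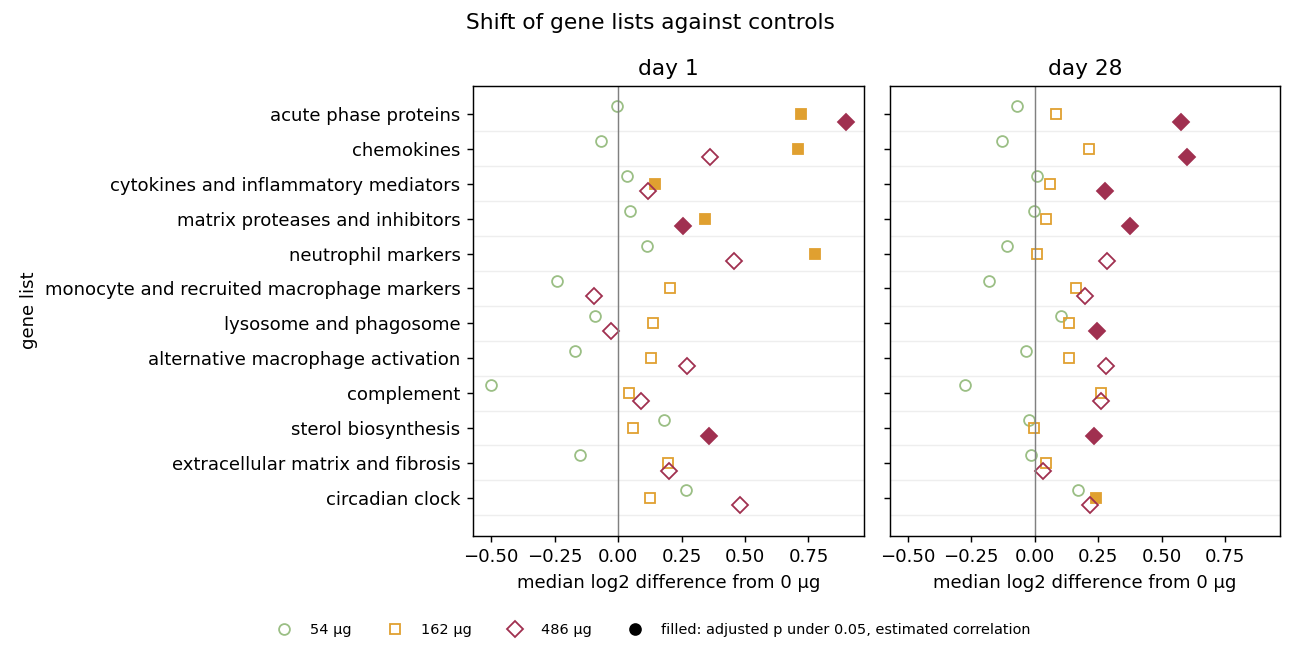
Median log2 difference from 0 µg (horizontal axes) of the members of 12 gene lists (vertical axis) at 54, 162 and 486 µg on day 1 and day 28, with filled symbols for an adjusted p under 0.05 with an estimated correlation. Acute phase proteins lie at 0.72 and 0.90 for 162 and 486 µg on day 1 and at 0.58 for 486 µg on day 28, and no symbol of 54 µg is filled.

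After 162 µg on day 28 clock genes shifted while no gene was called on its own. Dbp, a clock-controlled transcription factor, stood at 0.24 ± 0.42 against -1.44 ± 0.29 (n = 5 each), and Nr1d2, Nr1d1 and Tef differed by 1.14, 0.95 and 0.84. When adjusted over the list alone, 7 of 16 clock genes rose and 3 fell, and 0 did over all genes. The list had a median of 0.24 (camera adjusted p = 4.98e-07, 0.0105 with an estimated correlation, and fry adjusted p = 0.166), and its slide medians were 0.18 to 0.50 in the 4 slides that held both groups. Replicates 4 and 5 of this group were nearly alike (r 0.992), and with them averaged the list median was 0.24, while without replicate 1 of the controls it was 0.16. Per1 did not follow the other clock outputs, with -0.37 ± 0.30 (SE). The genes of smallest p were Cyp26b1, which degrades retinoic acid (2.52 ± 0.47, SE, adjusted p = 0.106), Dbp (1.67 ± 0.32, 0.106) and the endothelin Edn2 (-0.71 ± 0.14, 0.161, and -2.20 with the scanner's log ratio). In 16 alternatives Cyp26b1 passed in 5, Dbp in 4 and Edn2 in 3, with lowest adjusted p of 7.8e-05, 2.51e-04 and 0.00199. When slide was a block limma called 1 gene, Dbp (adjusted p = 0.0141), which was 1.06 to 2.41 higher within the 4 slides. The count of 0 in limma stood beside 255 genes at an unadjusted p under 0.05, and was 1 without replicate 1 (Cyp26b1) or 4 (Edn2) of the controls. Saa3 (2.04 ± 0.70) and Lcn2 (1.70 ± 0.47) were not past the threshold, each with an adjusted p of 1.00. Cardiac muscle markers had a median of -1.34 with 0 of 13 members above 0 (adjusted p = 1.43e-13, and 0.0955 with an estimated correlation), and adipose markers one of -0.90 (9.92e-04, and 0.339 with an estimated correlation), which was -0.45 without replicate 1 of the controls. Lysosome genes had a median of 0.14 with 25 of 27 above 0 (3.36e-08, and 0.0955), and red blood cell markers one of -0.52 with 0 of 6 above 0 (3.11e-05, and 0.144). Of 35 lists, 17 passed with the preset correlation, 1 with an estimated one and 0 with fry.

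At 54 µg on day 28 no gene was called. Edn2 (-0.72 ± 0.15, SE, adjusted p = 0.891, and -2.0 with the scanner's log ratio), Cyp26b1 (1.87 ± 0.50, 1.00) and the chaperone Dnajb1 (-0.73 ± 0.19, 1.00) had the smallest p and did not pass. Saa3 differed by -0.07 ± 0.74. The count was 0 in limma with and without slide as a block, with 499 and 440 genes at an unadjusted p under 0.05, and 1, Edn2, without replicate 4 of the controls. Of 35 lists, 10 passed with the preset correlation, and 0 with an estimated one or with fry. In the fit with slide as a block and an estimated correlation 1 list passed, the clock genes (adjusted p = 0.00989, median 0.18), of which 0 of 16 passed over the list alone without the block. Their median without the block, 0.17, was 0.07 without replicate 1 of the controls and 0.11 without replicate 1 of the 54 µg group. Cardiac muscle markers had a median of -1.13 (adjusted p = 6.97e-06, and 0.599 with an estimated correlation), and adipose markers one of -0.96 (0.00390, and 0.599), which were -0.72 without replicate 1 of the 54 µg group and -0.56 without replicate 1 of the controls.

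Between 486 and 162 µg no gene was called on either day, so the doses were not told apart gene by gene. On day 1 the smallest p belonged to Srprb (0.83 ± 0.19, SE), Cdk5rap1 (1.06 ± 0.25) and Tenm2 (0.48 ± 0.11), and on day 28 to Cd14 (0.92 ± 0.22), Akr1b8 (0.74 ± 0.18) and Ninj2 (0.38 ± 0.10), with an adjusted p of 0.999 on day 1 and 1.00 on day 28 in limma. Tenm2 was well above background on 2 of 4 arrays at 162 µg and on 5 of 5 at 486 µg. Counts at an unadjusted p under 0.05 were 978 and 437, and with slide as a block limma called 0 genes on either day (2820 and 667). The comparisons of 162 and 486 µg share their controls. On day 1, 3 genes were called at both doses in the same direction, against 0.00112 for independent lists of these sizes, which leaves out the shared controls, and 0 on average in 100 sets of simulated unchanged groups, which leave out the effects, so the excess is not read as a shared effect. The covariance of the log2 differences across genes was 0.0347, against 0.0248 for simulated unchanged groups with the same controls, and 0.00735 with the controls split between the doses. The correlation was 0.610 against 0.474 simulated, while the share of genes with the same sign was below its simulated value (64.7% against 65.7%). On day 28 there were 0 shared calls among 0 and 1, and the covariance was 0.0207 against 0.0246, and 0.00408 with split controls, with a correlation of 0.543 against 0.471 and 69.6% of genes of the same sign against 65.6%.

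The response at day 28 was not told apart from that at day 1 for any single gene. Genes of smallest p were Klf10 (0.87), Cbr3 (-0.99) and Edn2 (-0.64) at 54 µg, Asprv1 (-0.73), Cd14 (-1.0) and Cldn4 (-0.62) at 162 µg, and Hcn3, Srprb (-0.93) and Olfr572 at 486 µg. All of these day 28 minus day 1 values had an adjusted p of 1.00 in limma. Cbr3 differed by -0.44 without replicate 1 of the 54 µg group on day 28. No size is given for Hcn3 and Olfr572, which were well above background on 3 and 1 of the 9 day 28 arrays and on 7 and 5 of the 10 day 1 arrays of these groups. The counts were 0 in limma with and without slide as a block, with 314, 230 and 646 genes at an unadjusted p under 0.05 in order of dose. Of the 14 genes called at 486 µg on day 1, all 14 differed in the same direction on day 28 and 11 had an unadjusted p under 0.05 there, while 54.9% of all genes had the same sign at both days. Among lists at 162 µg, acute phase proteins and neutrophil markers differed between days with an estimated correlation and not with fry, with day 28 minus day 1 medians of -0.68 and -0.66 and a camera adjusted p of 0.0437 each. These were 0.240 and 0.142 with slide as a block and an estimated correlation. At 54 and 486 µg 0 lists differed with an estimated correlation, and 2 and 9 did with the preset one.

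In the controls, day 28 and day 1 differed in 0 genes by limma with and without slide as a block, with 1583 and 382 genes at an unadjusted p under 0.05, the larger count being that with the block. The smallest p belonged to Samd4b (0.54 ± 0.13, SE), Gucy1b2 (-0.29 ± 0.08) and Hcn3, which was well above background on 1 of 5 day 28 and 4 of 5 day 1 controls, each with an adjusted p of 1.00.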

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

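The test with slide as a block was set against the 14 genes called at 486 µg after the result was seen, as were the medians between days without single arrays, while the gap test within groups, the tests between days, the splits and the test of array weights were planned.

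The response of several gene lists differed between days by the preset-correlation test, given here as median day 28 minus day 1 differences. At 54 µg, lysosome genes differed by 0.157 and cell cycle genes by 0.309. At 162 µg, acute phase proteins (-0.684), neutrophil markers (-0.662), chemokines (-0.315), cytokines (-0.0795), matrix and fibrosis genes (-0.177), matrix proteases (-0.240), interferon response genes (-0.276), glucocorticoid response genes (-0.379), club cell markers (-0.224), smooth muscle markers (-0.328), cardiac muscle markers (-0.951) and red blood cell markers (-0.653) were lower on day 28, and alveolar macrophage markers (0.476) were higher. At 486 µg, chemokines (0.320), lysosome genes (0.248), interferon response genes (0.49), complement genes (0.368), recruited macrophage markers (0.239) and adipose markers (0.905) were higher, and alveolar type 1 cell (-0.399), endothelium (-0.609) and smooth muscle (-0.436) markers were lower. With fry 0 of these 24 differences passed. With an estimated correlation 2 passed, those of acute phase proteins and neutrophil markers at 162 µg (adjusted p = 0.0437 each). These 2, matrix proteases and red blood cell markers at 162 µg, lysosome genes at 54 µg and endothelium markers at 486 µg kept their median within 1.5-fold without any 1 array, and the other 18 did not. At 486 µg, without replicate 2 of the day 28 group the medians were 0.01 for interferon response genes, 0.06 for complement genes, -0.06 for recruited macrophage markers, 0.10 for lysosome genes and 0.17 for chemokines. Without replicate 2 of the day 1 controls they were -0.13 for adipose markers, 0.06 for complement genes and 0.07 for recruited macrophage markers. Without replicate 3 of the 162 µg group on day 1, interferon response genes at 162 µg were at 0.11 and chemokines at -0.12, and without replicate 4 cardiac muscle markers were at -0.49. Without replicate 1 of the 54 µg group on day 28, cell cycle genes at 54 µg were at 0.09.

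Single arrays stood apart from their group in 26 of 270 sets of 4 or 5 arrays tested (9.63%, where chance gives 5% of independent sets), by the gap to the nearest array over the range of the group. The sets come from 89 related genes or lists on the same arrays, so the share is not read as an excess. Replicate 2 of the day 1 controls did so for Lynx1 (0.865), Ly6c2 (0.813), Saa2 (0.874), Chchd10 (0.763), Spp1 (0.718), Srprb (0.893) and the acute phase list (0.760). Replicate 4 of the 486 µg group on day 1 did so for Timp1 (0.859), Asgr1 (0.730), Ptges (0.938), Spp1 (0.740), Fdps (0.827) and the sterol list (0.772). Replicate 3 of the day 1 controls did so for Il1rn (0.847), S100a8 (0.806), Ccl17 (0.712) and Trem1 (0.826). The others were Lgmn (0.948) and Akr1b8 (0.855) in replicate 4 of the 486 µg group on day 28, Idi1 (0.734) and Klf10 (0.810) in replicate 3 of the day 28 controls, Nr1d1 (0.760) and Klf10 (0.732) in replicates 3 and 1 of the 54 µg group on day 1, Klf10 (0.755) in replicate 1 of the day 1 controls, Olfr572 (0.890) in replicate 4 of the day 28 controls, and the recruited macrophage list (0.722) in replicate 2 of the day 28 controls.

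The 14 genes called at 486 µg on day 1 were weighed against slides that hold the groups unequally. With slide as a fixed block 38 genes were called over all genes, 7 of them among the 14. This argues against slide differences as the whole cause of those 7 calls and leaves them open for the rest of the 14. The block also raised limma's count at an unadjusted p under 0.05 between the controls of the 2 days, from 382 to 1583, so the larger total is not read as support. At 162 µg on day 1 and 486 µg on day 28 the block left 0 genes, against 3 and 1, and slide differences stay open there. Of 100 splits of the same 10 arrays, 1 gave as many genes, the real one, and the highest other split gave 10. These splits ignore slides and treat replicates 3 and 5 of the 486 µg group as separate animals, so they do not exclude chance. The count was 5 without replicate 3 or 5 of the 486 µg group or with these 2 arrays averaged, and no splits were made in those settings. With array weights 389 genes were called, but 5 of 50 splits weighted alike, the real one among them, gave as many and 1 gave 1181. Weights fitted to groups can therefore make such calls by themselves, and the larger count is not read as a response. A structure of the samples behind the split of 1181 was not tested. A response to the dose stays open for the 14 genes. Time of collection and a difference in how lungs were sectioned or trimmed were not tested for them and stay open too. For Chchd10 this includes fat in 1 control section. Replicate 2 of the day 1 controls stood apart for that gene and had an adipose marker score of 6.67.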

How the results depend on the processing

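The alternatives without scan day 1, without slide 4 and with the most alike arrays averaged were chosen after the results were seen, and the others were planned. No paired analysis was possible because the labels link no animals of different groups and replicate numbers only name arrays, and arrays of 1 slide were compared through slide as a block. Counts of called genes that moved by more than 1.5 times are given below for comparisons with 0 µg unless stated, against 3, 14, 0 and 1 genes at 162 and 486 µg on day 1 and at 162 and 486 µg on day 28. Without background correction there were 2 at 162 µg and 4 at 486 µg on day 28. With the scanner's log ratio there were 6 and 28 on day 1, and 1 and 36 on day 28. With the authors' processed values there were 6 at 162 µg on day 1 and 4 at 486 µg on day 28. A strict filter gave 3 at 486 µg on day 28, and every probe on its own gave 1 at 162 µg on day 1. Slide as a fixed block gave 0 and 38 on day 1, and 1 and 0 on day 28. Slide as a random block gave 6 and 64, and 3 and 16. Scan day as a block gave 55 and 8 at 486 µg on the 2 days. Array weights gave 0 and 389, and 11 and 11, and 21 genes for 486 against 162 µg on day 1. A fit over the compared groups gave 0 and 8, and 13 and 4, with 7 of the 8 and 0 of the 4 among the genes called before. Without scan day 1 there were 0 and 6 on day 1 and 0 at 486 µg on day 28. Averaging the 2 most alike pairs of arrays gave 0 and 5 on day 1. Leaving out 1 array gave 0 to 9 and 5 to 26 genes at 162 and 486 µg on day 1, and 0 to 1, 0 to 1 and 0 to 11 at 54, 162 and 486 µg on day 28. At 54 µg on day 1, for 486 against 162 µg on day 28, between days and in the controls, limma called 0 genes in all 17 alternatives and without any 1 array, with 471, 437, 314, 230, 646 and 382 genes at an unadjusted p under 0.05. No test changed direction. Of 28 list shifts, 3 had a median that turned negative: that of recruited macrophage markers at 162 µg on day 1 with the scanner's log ratio (-0.011) and without replicate 3 of that group (-0.07), and those of recruited macrophage markers (-0.13) and complement genes (-9.86e-04) at 486 µg on day 28 without replicate 2. For 116 results of named genes, 3032 alternative values held 2820 on the same side of the threshold, 112 weaker and 100 stronger, and for 28 list shifts 683 values held 641 and 42 weaker. At most 18 of the 116 gene results had passed over all genes. For a result that had not passed, the same side means not passing again. The pooled count of 2820 therefore does not show how stable the calls were.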

Other observations

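The tests of clock genes, cardiac muscle markers and adipose markers below, with their limits, were chosen after the results were seen.

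Cyp26b1, which degrades retinoic acid, lay above controls by 1.62, 1.79 and 0.27 at 54, 162 and 486 µg on day 1 and by 1.87, 2.52 and 2.29 on day 28. The 3 doses of a day share their controls, whose mean was 1.82 on day 1 and 0.96 on day 28, so the 3 values of a day are not independent. Edn2 differences on day 28 at 54 and 162 µg (-0.72 and -0.71) share 5 controls in the same way, and at 486 µg no size is given, as Edn2 was well above background there on 1 of 4 arrays. Edn2 stood at 0.16 ± 0.35 in the day 28 controls and at -0.34 ± 0.22 in the day 1 controls. Its means at 54 and 162 µg on day 28, -0.56 and -0.55, lay closer to the day 1 controls. A fall in exposed lungs is therefore not told apart from high day 28 controls. Neither gene passed limma's test over all genes at any of these doses before alternatives, with a lowest adjusted p of 0.106 for Cyp26b1 and 0.121 for Edn2. At 162 µg on day 28 Cyp26b1 passed in 5 and Edn2 in 3 of 16 alternatives, with adjusted p down to 7.8e-05 and 0.00199.

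Clock genes at 162 µg on day 28 may reflect tissue collected at another time of day, which the labels do not state. Genes driven by the clock were higher by 0.675 ± 0.158 (SE) and the Arntl set differed by -0.287 ± 0.0718, and the exact permutation p of the difference between the sets was 0.00794 over 252 splits (n = 5 each), or 0.0556 after adjustment over 7 such tests (0.883 ± 0.205 with the 2 most alike arrays of the group averaged, exact permutation p 0.00794 over 126 splits, the smallest they can give). The sets moved apart, but a tissue with other levels of both sets could give the same pattern, so this test cannot decide on a change in cell makeup. Cardiac muscle and adipose markers were lower in the same comparison. Per1, one of the genes driven by the clock, lay below controls on day 28 by -0.79, -0.37 and -0.37 in order of dose. The difference between the sets was 0.611, 0.695 and 0.893 on day 1 and 0.315, 0.962 and 0.715 on day 28 in order of dose, against shared controls of each day (exact permutation p adjusted over the 7 tests 0.0833, 0.0889, 0.0741, 0.102, 0.0556 and 0.0741, none under 0.05), and -0.247 ± 0.208 between 486 and 162 µg on day 28 leaves a dose trend undecided. An exact permutation p of 0.00794 is the smallest that these splits can give. With 1 test alone at that p, the adjusted value cannot be lower than 0.0556. The lack of values under 0.05 therefore does not count against a shift. Time of collection, a change in cell makeup and a response to the particles all stay open.

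Cardiac muscle and adipose markers had medians under 0 in all 6 exposed groups, 4 of the 6 past the preset-correlation test for cardiac and 5 of the 6 for adipose markers, and 0 with an estimated correlation (lowest adjusted p 0.0955 and 0.196). A control section with more heart or fat was weighed as a candidate cause, by the lowest share of a median past the preset-correlation test that was left without 1 control array. For adipose markers on day 1 this share was 0.0229, and replicate 2 of the controls (score 6.67, other controls 1.86 to 3.83, exposed arrays 0.36 to 3.82) accounts for most of the difference. For cardiac markers on day 28 it was 0.759, which argues against 1 section as the whole source, while 0.197 for cardiac markers on day 1 and 0.496 for adipose markers on day 28 leave it open there. All 5 controls lay above the median of the exposed arrays for cardiac markers on day 28. The same held for adipose markers on day 1 (lowest control 1.86, exposed median 1.57) and on day 28 (2.47 and 2.30). For cardiac markers on day 1, 4 of 5 controls did. Replicate 2 was therefore not the only day 1 control with a high adipose score. A difference in how lungs were sectioned or trimmed, and a difference in the animals, were not tested and stay open.

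Other splits of the same arrays were counted for each remaining comparison, with 100 splits each. At 162 µg on day 1, 1 split gave 3 genes or more, the real one, and the highest other gave 2. At 486 µg on day 28, 2 of 100 splits, the real one among them, gave 1 gene, the highest other being 1. Where 0 genes were called, all 100 splits gave at least as many by construction, so these counts say nothing about chance, and the highest other split gave 3 at 54 µg on day 1, 1 and 1 at 54 and 162 µg on day 28, 12 and 0 for 486 against 162 µg on days 1 and 28, 0, 10 and 25 for the differences between days at 54, 162 and 486 µg, and 0 in the controls. Limma's counts at an unadjusted p under 0.05 in these comparisons were 471, 440, 255, 978, 437, 314, 230, 646 and 382.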
